A study of Mus musculus with 10 samples.

How the data were processed

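Genomic DNA of whole mouse embryos at embryonic day 7.5 was measured by reduced representation bisulfite sequencing, 5 embryos labelled control and 5 labelled arsenic, per the labels. Per the labels' protocols, DNA was column-purified (Qiagen AllPrep) from the material of single embryos and libraries were made with a NEBNext Ultra II kit. The submitters' processing notes name Trim Galore, Bismark, methylKit and the mm10 build, with no versions. The role and settings of each tool, read deduplication and the handling of overlapping read mates are not given in the sources used here. These matter: a fragment read in both mates, or copied by PCR, and counted each time makes counts look more precise than they are. The arsenic dose and timing, the strain and the sex of the embryos are also not given in the sources used here.

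The deposited table holds read counts per CpG cytosine in columns named as methylKit names them, per the file headers: the coverage, the count of methylated reads and the count of unmethylated reads for each of 10 libraries. The values are not normalized. It was checked that methylated and unmethylated counts sum to the coverage everywhere and that every cytosine has a coverage of at least 10 in all libraries, so cytosines thinly read in any library are left out. The strands are not merged: 1196939 cytosines are on the plus strand and 1194856 on the minus strand. At the 755757 CpGs read on both strands the levels of the strands correlated with r 0.958 across CpGs, and at 0.740 among those of 20 to 80%.

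The column names carry only the numbers 1 to 10, so all 30 per-sample columns could be matched to no sample or group. Assigning them by order or by their values was ruled out. As a result none of the group tests planned before the data were examined was run. These were the permutation tests of global methylation, of level classes, of gene lists, of spread and of the sex chromosomes. The models for differential CpGs, 1000 bp windows and promoters were not run either. The comparison of repeats with other CpGs also needed a genome sequence, which was not used here. The planned rule named the genes with the largest group differences, at most 3 per list, and always H19, Peg3, Snrpn, Mest, Kcnq1ot1 and Plagl1. Without groups it was replaced, after levels had been seen, by the members at the ends of each list with examples between them, and the imprinted genes always named.

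A methylation level is the mean over cytosines of methylated reads over coverage. Pooled levels sum the counts of the 10 libraries at each cytosine first. Values are given with the range over the libraries. No mean with SD is given, since the libraries mix the groups. The SD of the 10 libraries served only to judge shifts under other settings. Wilson 95% intervals take each count at each cytosine as an independent molecule. Reads carry no molecular identifiers, a read counts at every CpG that it spans, and both mates may be counted. The intervals are therefore too narrow even for counting error. Chromosome X and Y were kept apart from the autosomes.

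Genes came from the RefSeq annotation of GRCm38.p6, which has the coordinates of mm10. Of its 49997 gene symbols, 24177 autosomal ones had a measured end. The annotation was used without strand, so promoters could not be placed. The planned promoter was replaced, after the table had been opened but before levels were seen, by the cytosines within 1000 bp of the gene end that has more of them, at least 3, with genes of an identical window counted once per list. The 12 gene lists were fixed before the data were examined, and 6 more (olfactory receptors, ribosomal proteins, replication-dependent histones, keratins, zinc finger genes with Zfp symbols and serpins) were added after the data were seen but before their values were. A list's median was placed among the medians of 10000 random lists of windows matched in 10 classes of cytosine number. The random windows came from all gene classes, pseudogenes and long noncoding RNA genes included, so a percentile can also reflect the gene class. The percentile describes these libraries and is not a test between groups.

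Heterogeneity over the 10 libraries was tested per autosomal CpG of 5 to 95% pooled level by a chi-square test with 9 degrees of freedom and Benjamini-Hochberg adjustment, and again with the statistic divided by 2 as if each fragment were counted in both mates. Windows of 1000 bp needed at least 10 cytosines and a mean coverage of 20 in every library, limits that were set after the data were seen. Correlations within a cluster of libraries used exact permutation tests and those over all 10 libraries used 100000 permutations, 2-sided. On 20000 simulated CpGs with the real levels and coverage, the chi-square test recovered 32.0% of 100 CpGs shifted by 20 points in 5 libraries and 92.0% of 100 shifted by 40 points, with 7 false calls. In 200 lists drawn from simulated windows, 6.00% of unchanged lists fell outside the central 95% and all lists raised by 20 points exceeded it. That recovery applies to the simulated windows and need not hold for the real lists. The central 95% of real random lists was 2.41% to 51.4% around 19.1% for visceral endoderm genes. It was 1.77% to 54.2% around 15.5% for blood genes, so a list raised by 20 points could stay inside. It was narrower for other lists, such as 1.63% to 6.81% for Hox genes.

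The alternative settings fixed beforehand and run were a coverage minimum of 20, methylated reads over all reads, thinning to 10 reads and leaving out each library. Added after seeing the data were the removal of cytosines above the 99.9th percentile of coverage, plus-strand cytosines only, both gene ends together, at least 5 cytosines per window, 500 bp windows and halved counts. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.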

Results

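DNA methylation was profiled by reduced representation bisulfite sequencing, an assay in which a restriction enzyme enriches CpG-rich fragments and bisulfite converts unmethylated cytosines before sequencing. The samples were 10 mouse embryos at embryonic day 7.5, the stage of gastrulation, of which 5 were labelled as controls and 5 as arsenic, in the study's experiment 2. The design asked whether the methylation of control and arsenic embryos differed. That comparison was not made here, because the table of counts numbers its 10 libraries only from 1 to 10 while the labels number control embryos 1 to 5 and arsenic embryos 1 to 5, so no library could be tied to an embryo or to a group. The values below therefore describe all 10 libraries together, each as a level pooled over the 10 libraries with the range over the libraries, and say nothing of an effect of arsenic. Library numbers are the table's own and are not the replicate numbers of the labels.

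The table held 2391795 CpG cytosines, each covered by at least 10 reads in every library. Summed over these cytosines, coverage ran from 94583116 to 127102232 reads per library, with a median of 116251972, where a read that spans several CpGs counts at each. Median coverage per cytosine was between 30 and 42 reads. Levels of autosomal cytosines correlated between libraries with a Pearson r of 0.917 to 0.930 over the 45 pairs of libraries, across cytosines, which are not independent replicates. No 2 libraries held identical counts.

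The assayed autosomal CpG cytosines were on average 41.6% methylated, and the 10 libraries lay within 2.57 points of each other, from 40.3% in library 1 to 42.8% in library 2, with a median of 41.8%. The assay enriches CpG-rich sequence, and 31.3% of these cytosines lay within 1000 bp of a gene end. The mean is therefore not a level of the whole genome. Among the assayed cytosines, low and intermediate levels dominated. Of the 2346489 autosomal cytosines, 33.4% were under 20% methylated, 56.6% were between 20 and 80%, and 10.003% were over 80%. Chromosome X had a mean level of 48.0%, with a range of 46.8% to 49.0% over the libraries. Among autosomes the mean level ran from 37.1% on chromosome 11 to 44.0% on chromosome 10. With a coverage minimum of 20 in every library the mean autosomal level was 43.3%, above the 42.8% of the highest library at the minimum of 10. The shift was smaller than the range over the libraries but larger than their SD.

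**Figure D1:**
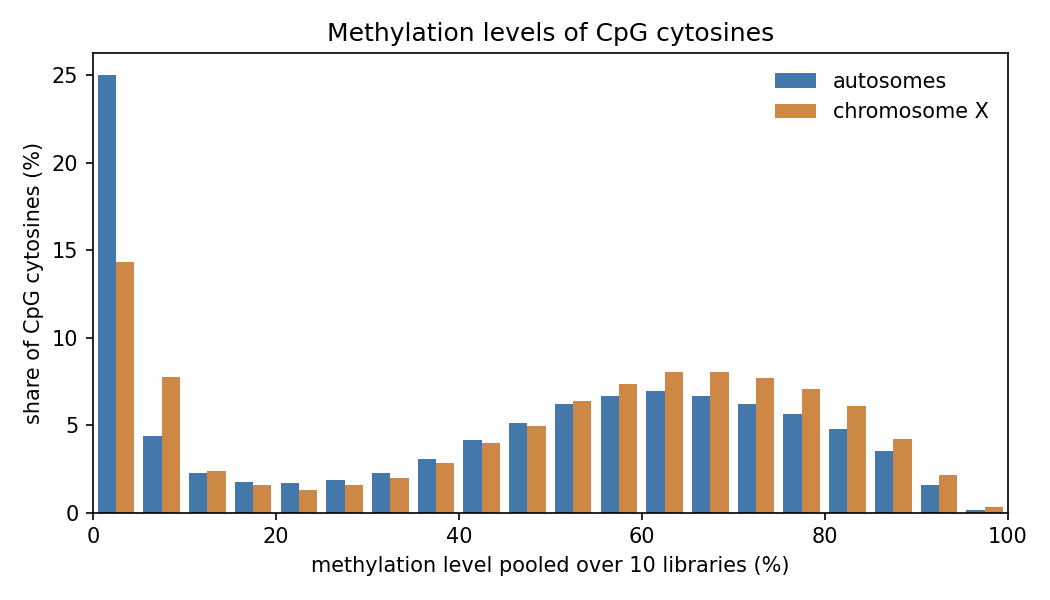
Distribution of methylation levels, pooled over the 10 libraries, of 2346489 autosomal and 41785 chromosome X CpG cytosines, in bins of 5 points; bars give the share of cytosines per bin (%). The bin from 0 to 5% held 25.03% of autosomal and 14.3% of X cytosines, and most others spread around a broad peak at 60 to 65% on the autosomes.

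Methylation was low around gene ends and in CpG-dense sequence, and higher elsewhere. Cytosines within 1000 bp of an annotated gene end averaged 16.1% (15.6% to 16.5% over the libraries), those further inside genes 52.6% (51.1% to 54.1%), and those outside genes 54.4% (52.4% to 56.2%). Windows of 1000 bp with 60 or more assayed cytosines averaged 4.97%, and windows with 1 to 9 averaged 56.2%. The ranges of the low and high places did not overlap in any of these contrasts. Gene classes differed as well. The median level of gene windows, each the 1000 bp on either side of the gene end with more assayed cytosines, was 3.69% for 13292 protein-coding windows and 1.81% for 202 windows at tRNA genes, against 47.1% for 5483 windows at long noncoding RNA genes and 58.99% for 2249 at pseudogenes. Of the protein-coding windows, 74.1% were under 20% methylated. The medians of the gene classes were not matched on the number of cytosines per window. The contrast between classes was therefore not told apart from one of CpG density. The annotation used here gave gene starts and ends without strand, so the window can lie at either the 5' or the 3' end of a gene, and whether a cytosine is exonic, intronic or in a UTR was not analysed here.

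Genes controlled by parent-of-origin imprints, where methylation inherited from 1 parent marks a single allele, sat near the middle of the scale. The maternally methylated imprinted genes had a median of 43.5% over 22 distinct windows, and 14 of these windows lay between 35 and 65%. This median was at the 99.95th percentile of 10000 random lists of windows matched on their number of cytosines, whose own median was 5.52%. Levels of 35 to 65% were not particular to imprinted genes. They were found in 15 of 26 germline and 69 of 81 olfactory receptor windows, but in 1 of 37 Hox and 0 of 25 arsenic and oxidative stress windows. H19, an imprinted noncoding RNA gene on chromosome 7 (142575530 to 142578146), was 47.8% methylated over 15 cytosines, with a range of 44.4% to 53.5% over the libraries. Its counts summed over these cytosines and the libraries came to 11118 reads, of which 48.4% were methylated (95% Wilson interval 47.4% to 49.3%). This interval is too narrow, since a read counts at every CpG that it spans. The read numbers and the interval below were obtained alike. Peg3, which encodes a zinc finger protein and lies on chromosome 7 (6703892 to 6730462), was at 39.6% (22.3% to 53.6%) over 16 cytosines that it shared with Usp29, with 3189 reads (40.04% methylated, 38.4% to 41.8%). Mest, on chromosome 6 (30733506 to 30748466), was at 44.6% (31.4% to 60.9%) over 11 cytosines and 1742 reads. Kcnq1ot1, a noncoding RNA gene on chromosome 7 (143213111 to 143296547), was at 41.1% (27.3% to 58.4%) over 13 cytosines and 7149 reads, and Plagl1, on chromosome 10 (13090832 to 13131694), was at 51.5% (44.4% to 67.7%) over 37 cytosines and 11902 reads. Snrpn had no window with at least 3 cytosines, and Snurf, encoded by the same transcription unit, was at 51.0% (43.1% to 60.3%) over 34 cytosines. The other 8 windows were H13 at 2.92%, Grb10 at 3.76%, Inpp5f at 9.93%, Ndn at 11.6%, Igf2r at 18.1%, Mkrn3 at 21.6% and Gnasas1 at 34.6%, and at the other end Peg13 at 68.9%. The 6 measured genes of the paternally methylated list had a median of 43.0%, the 89.6th percentile of random lists, with Meg3 at 39.8% (35.3% to 43.9%), Igf2 at 46.2% over 3 cytosines, Zdbf2 at 66.3%, Rasgrf1 at 4.67% and Dlk1 at 1.44%. In both lists the window was the gene end with more assayed cytosines, which need not hold the region that carries the imprint. A low level at such a window therefore does not show that an imprint was missing.

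**Figure D2:**
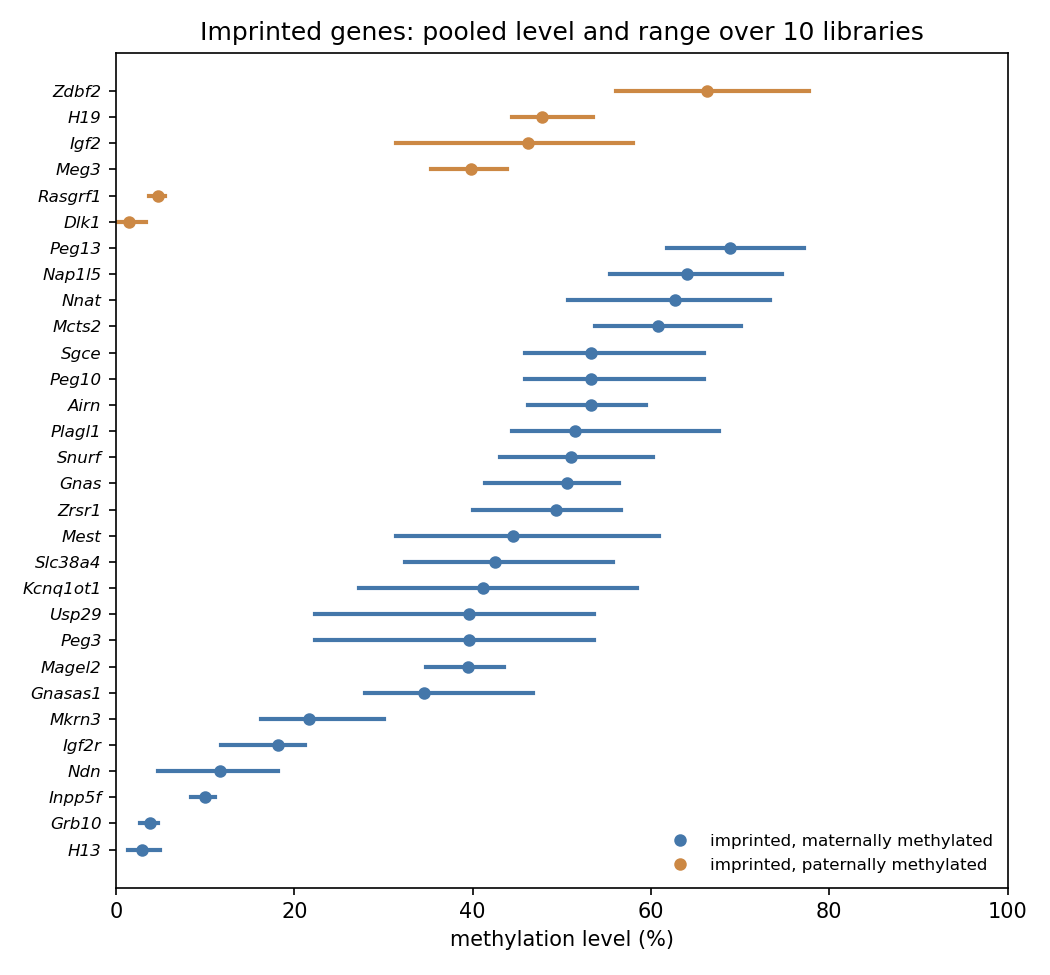
Methylation level (%) at the gene windows of the imprinted lists; points are levels pooled over the 10 libraries and bars run from the lowest to the highest library, blue for maternally and orange for paternally methylated genes. H19, Snurf, Plagl1 and Airn lie close to 50%, while Grb10, H13, Rasgrf1 and Dlk1 lie under 5%. A window need not hold the region that carries the imprint.

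Germline genes, which act in germ cells and are silenced in somatic cells, were the most methylated of the 12 gene lists fixed before the data were examined. Their median was 53.3% over 26 windows (49.9% to 57.5% over the libraries), the 99.97th percentile of random lists, and 25 of the 26 windows were at 20% or more. Sohlh2, a transcription factor of early oocytes and spermatogonia, was at 76.5% (73.4% to 79.9%) over 36 cytosines. Dpep3, a testis-expressed dipeptidase, was at 82.2% over only 4 cytosines, with a range of 59.6% to 97.4%. Tuba3a was at 72.3% and Mov10l1, a helicase of the piRNA pathway, at 69.4%. Mael and Sycp1, which act in piRNA silencing and the synaptonemal complex, were at 53.5% and 53.2%. Dazl and Ddx4, regulators of germ cell RNA, were lower, at 34.6% (31.1% to 37.5%) and 34.7% (26.7% to 47.0%), and Stag3, a meiotic cohesin subunit, was the exception at 11.6%.

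Lineage genes were split. Pluripotency genes had a median of 31.0% over 15 windows, the 99.45th percentile of random lists. Sox2, Tbx3, Klf4 and Utf1 were under 2% (Sox2 1.17%, Utf1 1.93%), while Pou5f1 was at 30.9% (21.9% to 38.9%), Zfp42 at 34.3%, Dppa3 at 39.0% and Dppa4 at 44.8%. Gastrulation genes had a median of 8.68% over 16 windows (97.4th percentile). T, Mesp1, Nodal, Lhx1 and Mixl1, transcription factors and a ligand of the primitive streak, were under 5%. Gsc was at 28.5%, and Msgn1 and Bmp4 were at 63.8% (58.1% to 69.5%) and 70.3% (65.6% to 73.0%). Without strand, some windows of a list can lie at 5' ends and others at 3' ends, so these contrasts need not be between promoters. Trophoblast genes had a median of 2.81% (43.9th percentile), from Tead4 at 1.01% and Cdx2 at 1.17% to Gcm1 at 53.8%; the median was 4.68% with both gene ends together and 4.62% within 500 bp. Visceral endoderm genes had a median of 17.8% (47.2nd percentile), from Gata6 at 5.22% to Cer1 at 58.6%, and blood genes had a median of 40.7% (89.7th percentile) over 8 windows, from Tal1 at 2.14% to Runx1 at 72.1%. With a coverage minimum of 20 the blood median was 24.99%.

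The genes of the DNA methylation machinery were mostly unmethylated at the measured end, with a median of 2.58% over 15 windows, the 23.8th percentile of random lists, and 12 windows under 5%. The median was 1.64% with a coverage minimum of 20 and 1.52% within 500 bp of the gene end. Trim28, a co-repressor that maintains imprints, was at 0.492% and Tet1, a methylcytosine dioxygenase, at 0.875%. The exceptions were Dnmt3l at 44.1%, Hells at 78.9% over 5 cytosines and Zfp57 at 80.3% over 7 cytosines. The genes of arsenic metabolism and oxidative stress had a median of 1.84% over 25 windows, at the 8.9th percentile of random lists, and 17 of the 25 were under 5%. With both gene ends together the median was 4.04%. Nfe2l2, the oxidative stress transcription factor NRF2, was at 0.722%, Keap1, its inhibitor, at 0.988%, the metallothionein gene Mt2 at 1.07% and Hmox1 at 2.61%. Aqp9, an aquaglyceroporin that carries arsenite, was at 70.7% (66.7% to 74.6%), and Aqp3 was at 33.0%. Here too a window can lie at the 5' or the 3' end, so a high level need not be that of a promoter. Both percentiles describe all 10 libraries, in which control and arsenic embryos are mixed.

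Hox genes, which pattern the body axis, had low but not minimal levels, with a median of 7.89% over 37 windows at the 99.1st percentile of random lists. They ran from Hoxd8 at 0.811% to Hoxd4 at 37.3% (33.7% to 46.9%), and 32 of the 37 were under 20%. The clustered protocadherins, cell-adhesion genes of neurons, had a median of 22.4% over 37 distinct windows (89.8th percentile), from Pcdhgc3 at 2.75% to Pcdhb17 at 47.9%.

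**Figure D3:**
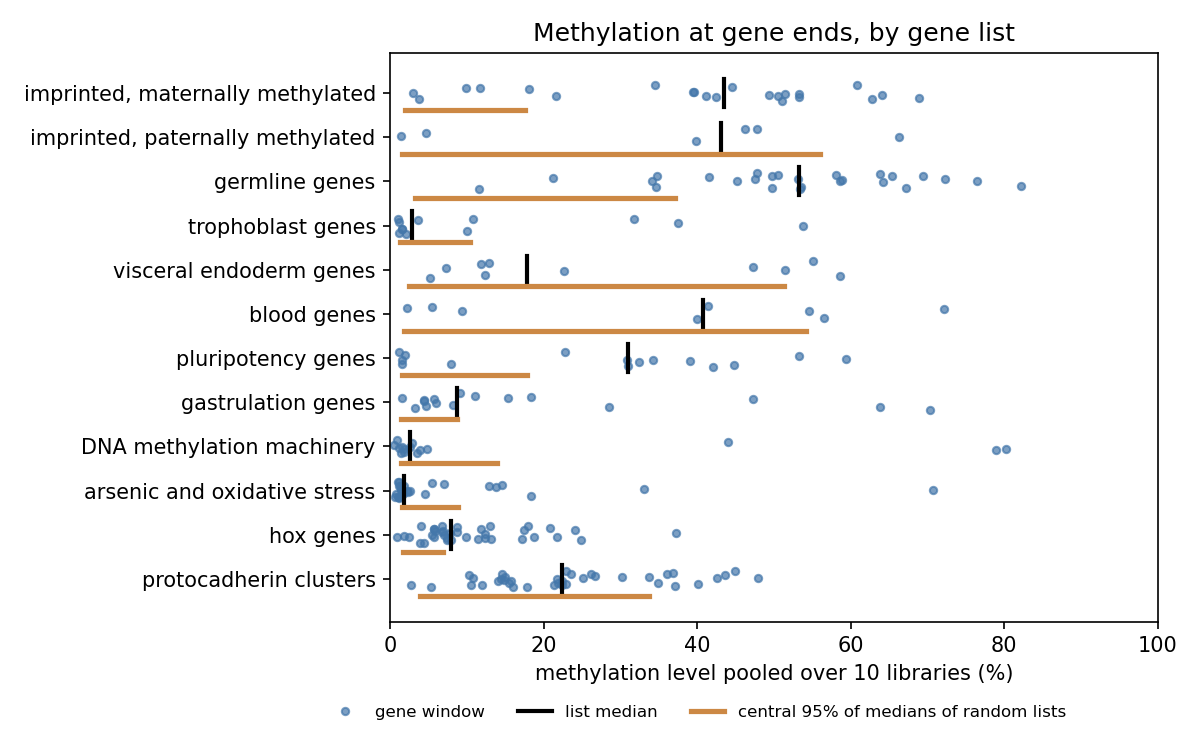
Methylation level (%) of the windows of the 12 gene lists fixed before the data were examined; each blue point is a gene window pooled over the 10 libraries, black bars are list medians, and orange bars span the central 95% of the medians of 10000 random lists matched on the number of cytosines. The medians of the maternally methylated imprinted, germline, pluripotency and Hox lists lie above their orange bars.

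How far the libraries differed at single CpGs beyond read counting depended on how reads are counted. Over 1755343 autosomal CpGs with a pooled level of 5 to 95%, the median range between the lowest and highest library was 28.1 points, against 21.5 points in data simulated from the pooled level and the same coverage and 30.4 points with that coverage halved. The median dispersion was 1.58, against 0.933 simulated from counting, and among CpGs at 30 to 70% it was 1.35 where both counts were even in 0 to 2 libraries. A chi-square test of homogeneity over the 10 libraries, with Benjamini-Hochberg adjustment, called 446471 of these CpGs (25.4%) at an adjusted p under 0.05, and 1522 (0.0867%) when the counts were halved. The reason for halving is that many pairs of methylated and unmethylated counts were both even, as they would be if each fragment were counted in both of its reads. Neither number is a difference between the study's groups.

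The median range over 51506 autosomal windows of 1000 bp with at least 10 cytosines was 11.9 points. A mean over many cytosines has a smaller range than a single one by construction, so this is not set against the range at single CpGs. A test that takes each window's mean coverage, halved, as its number of fragments called 6 windows at an adjusted p under 0.05 and 17 at an unadjusted p under 0.05, where 2575 would be expected by chance from a test of the right size. The test is therefore too strict to pass windows of ordinary depth, and a window that it did not call is not shown to be alike in the libraries. All 6 were very deeply read, with mean coverages in the least covered library of 2469 to 43452 reads. Windows in the Rn18s-rs5 gene, a ribosomal RNA repeat on chromosome 17, ranged from 14.2% to 24.4% (39846000 to 39846999) and from 7.39% to 12.9% (39848000 to 39848999). A window within Cmss1 on chromosome 16 (57391000 to 57391999) ranged from 14.1% to 20.2%. A window on chromosome 6 (3201000 to 3201999), 2489 bp from LOC115490388, ranged from 32.7% to 48.2%. In each of these windows on chromosomes 17, 16 and 6, library 7 was the lowest and library 6 the highest. They need not be separate signals, and whether reads from repeated sequence map to them was not tested. The 2 windows on chromosome 2 lay in the deepest region of the table, 39600 and 35600 bp from Gm33780, and ranged over 5.23 and 3.79 points. The widest ranges lay elsewhere, in Lhfpl3 on chromosome 5 (22787000 to 22787999; 16.5% to 66.9%) and Snd1 on chromosome 6 (28928000 to 28928999; 25.2% to 74.6%), with mean coverages in the least covered library of 28 and 24.6 reads, a depth at which that test decides nothing.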

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

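The tests of the level differences and of male DNA were chosen after their results were seen; the dense-window test of the X was planned before.

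Reads on the Y chromosome stood out, because the labels give no sex and the main measurement used autosomes only. Every library had at least 137096 reads at Y CpGs, and the median coverage at CpGs of the first 4000000 bp of the Y was at least 25 in every library. The coverage minimum of 10 forces any such median to 10 or more, and the reads that an absent Y would give were not measured. Since the table keeps only cytosines read at least 10 times in every library, Y CpGs could be in it only if every library had reads mapped to them. The ratio of median coverage on this part of the Y to that on the X was between 0.9375 and 1.13 over the libraries. This ratio does not settle whether every library is from male DNA, since the coverage minimum keeps a Y CpG only where all libraries read it well. A library with little Y DNA would remove such CpGs or leave them near the minimum of 10. At the 595 CpGs kept the median coverage was 25 to 34 over the libraries, against 24 to 32 on the X. These values argue against a library with little Y DNA, unless reads from other chromosomes map to these CpGs, which was not tested. Female DNA in the libraries, from maternal tissue for instance, stays open too. The X's windows of 30 or more cytosines had a median level 2.439 points above that of the autosomes (5.28% against 2.84%), under the 5 points set beforehand, but that limit assumed a methylation level of inactive X islands at this stage that was not measured here, so it excludes no share of female DNA. Also open is the coverage of the X relative to the autosomes, 0.732 to 0.806, which the coverage minimum may have raised by removing thinly read X positions. Whether the DNA was all male or mixed with female DNA was thus not settled, and no other biological explanation was tested, since the design names no sex.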

How the results depend on the processing

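No paired analysis was possible because no column could be tied to a sample, so the replicate numbers of the labels belong to no library; the other settings planned for the differential tests and of centred list levels were not run for the same reason, and class shares have no read-weighted form. The alternatives beyond the coverage minimum, read weighting, thinning and left-out libraries were chosen after seeing the data. A value counts as moved when it shifted by more than the SD of the 10 libraries, and a count when it changed by over 1.5 times; the causes of the shifts were not tested unless stated. Leaving out each library moved none of the 19 values (190 recomputations): the autosomal level stayed at 41.5% to 41.8% and the heterogeneous CpGs numbered 395555 to 401568. Leaving 1 of 10 libraries out of a pooled mean can shift it by only a fraction of that SD. For mean levels this outcome was therefore fixed by the rule, and it is little evidence of stability for the other values. With a coverage minimum of 20, 11 of 19 moved: the autosomal level to 43.3%, the shares under 20% and of 20 to 80% to 30.8% and 58.7%, chromosome X to 49.7%, and the medians of the paternally methylated imprinted (47.0%), trophoblast (2.13%), visceral endoderm (15.0%), blood (24.99%), methylation machinery (1.64%), Hox (10.2%) and protocadherin lists (17.9%). With methylated reads over all reads, 4 of 15 moved: X to 48.8%, Y to 66.3%, visceral endoderm to 25.9% and blood to 37.5%. With both gene ends together, 6 of 12 lists moved: trophoblast 4.68%, blood 35.1%, machinery 3.82%, arsenic and oxidative stress 4.04%, Hox 11.2% and protocadherin 28.5%. Within 500 bp, 9 of 12 moved: maternally methylated 49.3%, paternally methylated 32.5%, trophoblast 4.62%, visceral endoderm 14.6%, blood 36.0%, gastrulation 6.54%, machinery 1.52%, arsenic and oxidative stress 1.35% and protocadherin 16.0%. With at least 5 cytosines, paternally methylated moved to 39.8% and visceral endoderm to 12.9%. The germline and pluripotency medians moved under none of these settings. Plus-strand cytosines alone or removal of the deepest cytosines left the autosomal level within the SD. The number of heterogeneous CpGs was 446471 as deposited, 1522 with counts halved and 1245 with each CpG thinned to 10 reads; both settings leave the test fewer reads.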

Other observations

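The even-count dispersion test was planned before its result was seen; the tests of zeros, conversion and depth, and the choice of genes in the next paragraph, came after.

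Genes whose close relatives were almost unmethylated stood out where they are germ cell versions of common genes. Ribosomal protein genes had a median of 1.332% over 69 windows, the 0.02nd percentile of random lists, but Rpl10l and Rpl39l, paralogs expressed in testis, were at 62.5% (58.1% to 69.98%) and 65.4% (61.5% to 70.3%). Replication-dependent histone genes had a median of 1.77% over 28 windows (0.03rd percentile), but the shared window of H2ac1 and H2bc1, the testis-specific pair, was at 59.6% (54.3% to 65.8%) over 54 cytosines. Rpl3 at 63.8%, over 10 cytosines, was high too, so the contrast is not limited to testis paralogs. Rpl6l at 56.8% is annotated as a pseudogene, a class whose windows had a median of 58.99%. Of 3610 protein-coding windows with at least 60 cytosines, 3528 were under 20% methylated and 17 were over 50%. In order of level these 17 were Pias4 (78.5%), Rab4a (76.2%), Zglp1 (73.2%), D1Pas1 (68.2%), Cpt1b, Col6a2, Grin3b, Oxct2b (59.4%), Urm1, Cercam, Gdf1, Upf1, Ccin, Tmem267, Habp2, Fam50b and Bnipl (50.7%). D1Pas1, an RNA helicase gene, Oxct2b, a ketone body enzyme gene, and Ccin, a sperm head protein gene, are expressed in testis, while Pias4, Rab4a and Upf1 are broadly expressed. The annotation without strand does not tell whether a 5' or a 3' end was read, so these need not be promoter levels. The windows of Urm1 and Cercam overlap, as do those of Gdf1 and Upf1. No list of testis genes was tested for enrichment in them.

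Among the other added lists, zinc finger genes with Zfp symbols had a median of 2.63%, below the medians of all 10000 random lists, with exceptions such as Zfp566 at 87.2%. The random lists were not matched on gene class, and the median of all protein-coding windows was 3.69%. Olfactory receptors were at 52.5% (50.1st percentile), serpins at 48.4% (54.0th percentile) and keratins at 50.1% (94.5th percentile), where 7 of the 36 keratin windows were under 20%: Krt18 at 3.60%, Krt88 at 5.76%, Krt19 at 5.84%, Krt90 at 7.06%, Krt87 at 12.9%, Krt222 at 15.7% and Krt7, the highest of these 7. Only 81 of 1111 autosomal olfactory receptor genes, 19 of 68 serpin genes and 36 of 50 keratin genes had a measured window, so these levels describe the measured genes alone.

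Both counts of a CpG were even more often than independent counts give. Of CpGs at 30 to 70%, 33.52% to 36.3% per library had even counts of both kinds, against 25% expected, which argues against the zeros of unmethylated CpGs as the whole reason. CpGs even in all 10 libraries numbered 7908 (0.818%, against 9.54e-05% expected), and their median dispersion between libraries was 1.797 times that of CpGs even in 0 to 2 libraries (2.43 against 1.35). This is consistent with both mates of overlapping read pairs being counted at the same CpG, in part of the table. The precision of the chi-square test is then overstated where this happened. Halving all counts corrects too much, since the observed median range of 28.1 points lies below the 30.4 points simulated with halved counts, and CpGs even in 0 to 2 libraries still had a dispersion above the 0.933 simulated from counting over all tested CpGs.

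The mean autosomal levels of libraries 1 to 10 were 40.3, 42.8, 41.4, 42.7, 42.2, 41.8, 40.7, 41.9, 40.4 and 42.2%. Libraries 1, 7 and 9 stood apart from the others: their levels at CpGs over 80% were 84.94, 84.97 and 84.95%, with the others at 85.9% or more, and their shares of reads in the deepest chromosome 2 region were 2.79, 2.40 and 2.35%, with the others at 3.12% or more. A difference in bisulfite conversion is argued against as the whole cause: lost methylated calls would scale all levels alike, but the highest library exceeded the lowest 1.077-fold at CpGs of 20 to 80% and 1.021-fold at those over 80%, a gap of 0.0562. Incomplete conversion would add most to unmethylated CpGs, but the libraries ranged over 0.344 points at CpGs under 20% and over 4.16 points at those of 20 to 80%. Depth cannot be told apart, because the libraries fall into clusters and the largest is small. In the 7 libraries above the 2 widest gaps of the chromosome 2 share, the level and total coverage had Pearson r -0.5225 (exact permutation p 0.232, adjusted 0.404 over 2 relations) and Spearman rho -0.464 (exact permutation p 0.302, adjusted 0.444), with r -0.293 without the 2 libraries farthest from the median. With a split at the widest gap alone, 8 libraries gave r -0.595 (exact permutation p 0.115, adjusted 0.115) and rho -0.571 (exact permutation p 0.151, adjusted 0.302). Without the 2 libraries farthest from the median, r was -0.620 in these 8 libraries and -0.534 over all 10. The other relation, of the level with the chromosome 2 share, had r -0.383 (exact permutation p 0.404, adjusted 0.404) and rho -0.357 (exact permutation p 0.444, adjusted 0.444) in the 7 libraries, and its sign turned in the 8 libraries, with r 0.654 (exact permutation p 0.114, adjusted 0.115) and rho 0.0952 (exact permutation p 0.840, adjusted 0.840). Over all 10 libraries, which were computed first, the level was lower with more coverage and higher with a larger chromosome 2 share by Pearson's correlation (permutation p 0.0421, adjusted 0.0421, and 0.0105, adjusted 0.0209) but not past 0.05 by Spearman's (permutation p 0.0974 and 0.143, adjusted 0.143 for both), and these pooled relations mix the libraries that stand apart with the rest. The way of splitting was chosen after the values were seen. Arsenic was not tested as the biological explanation, since the libraries could not be assigned to groups. An earlier test that thinned each CpG to 10 reads gave a range of 2.57 points before and after; it was set aside because thinning leaves a mean level where it was.

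The 2 deepest regions took 2.98% of reads (chromosome 2, 98662265 to 98667326, level 59.6%) and 1.89% (chromosome 17, 39841800 to 39848710, around Rn18s-rs5, level 15.3%). The level of the ribosomal region was 11.9% in library 7, the lowest, and 18.4% in library 6, the highest.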
